A study of Mus musculus with 3 samples.

How the data were processed

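Polyadenylated RNA of NSC-34 cells was made into sequencing libraries with a stranded mRNA kit, per the labels' protocols. The raw counts were made by the authors with the gene counting option of the aligner STAR, per the file headers, and are whole reads per gene without normalization. The RPM columns hold the counts scaled to each library's mapped reads, per the file headers, and were used only to check the totals. The authors' table of the clones against the control was made with DESeq2, per the file headers, and gives an absolute fold ratio, a log2 fold change with its standard error, a p-value and a Benjamini-Hochberg adjusted p-value. The file headers name STAR 2.5, the Gencode annotation M16 (Ensembl 91) and GRCm38/mm10, and the submitters' processing notes name bcl2fastq, STAR 2.5.3 and DESeq2. Which strand setting the counting used is not given in the sources used here, so reads of overlapping and antisense genes may be mixed. Reads shared between near-identical genes may also be missing or split.

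The groups came from the labels: 1 untreated library and 2 libraries of PR20-resistant clones. The file lists 22976 genes. Low counts were removed with filterByExpr on the groups, which left 13705 genes. Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main test was edgeR's quasi-likelihood F test, two-sided, with TMM factors, the quasi-likelihood method of edgeR version 4 (the legacy option off, which is not this version's default) and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was approximated as its size over the square root of F. With 1 control, the spread rests on 1 residual degree of freedom from the clones, moderated across genes. On simulated data for these 13705 genes, 50 genes with a mean CPM of at least 1 were changed at each fold. The edgeR test recovered 54% of genes changed 1.25-fold, 62% at 1.5-fold, 78% at 2-fold and 98% at 4-fold, with 3 false calls. It made 0 calls with no effect. The simulated control was given the spread estimated from the clones, so these rates hold only if the real control varies like the clones.

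Log2 ratios of single clones used a prior count of 1. Chance levels for the agreement of the clones came from 20 simulations without effects, in which the simulated clones shared a simulated control. That control was given the spread estimated from the clones, so these levels hold only if the real control varies like them. A gene at 0 in both clones was given a bound from a floor of 3 counts over the group. Intervals are 95%. The bootstrap interval of the lineage transcription factors covers the spread among the chosen genes. The other intervals cover counting error only, as do floors, since reads without molecular identifiers are not independent molecules. Totals between 11307034 and 11700755 counts set this precision.

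The 43 gene lists, the design, the tests and most alternatives were fixed before the data were examined. Of the lists, 41 had at least 5 tested members and were tested with camera at an inter-gene correlation of 0.01, and 20 passed. With a correlation estimated from the data, 0 of these 20 calls held. That setting rests on 1 residual degree of freedom and has little power. Lists that passed and lists that did not, such as MYC and its targets, had the same adjusted p of 0.689 there. For the neuronal cytoskeleton and synapse list the estimated correlation was -0.010, below the preset one, so its loss did not come from a higher correlation. The genes named are the 10 called genes with the largest log2 fold change in each direction with a mean of at least 5 CPM and both clones on the same side, examples from up to 4 members per list with the lowest edgeR p, and the 5 genes higher in each clone. Predicted genes were counted and not named, and some genes that the rules select are not reported here. Mapt, Prph and Gm42418, and genes in the closing observations, were chosen after their values were seen.

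Alternatives were DESeq2's test, RLE size factors, no low-count filter, a mean CPM of at least 1, robust and legacy quasi-likelihood fits, limma-voom, a prior count of 5, fry, camera on ranks, an estimated correlation, and leaving out each clone. With a clone left out, the edgeR fold change of the remaining clone was taken with the dispersions of both clones. That estimate replaced the prior-count ratio after results were seen. In the plan, the alternatives of the gene set tests and of the correlation between clones were listed under each other's name, and each was run on the result it fits. Chosen after seeing the data were preset variations of 10% and 20% with edgeR's likelihood ratio test, the removal of chromosomes 7, 15, 18 and X, no filter together with the legacy fit, and no filter for the correlation of the clones. Gene positions, GC content and transcript lengths came from Gencode M21 on GRCm38, which covered 13692 of the 13705 genes, and were not used for the counts.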

Results

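Messenger RNA of NSC-34 cells was sequenced in 3 libraries. NSC-34 is a mouse hybrid line made by fusing neuroblastoma with spinal cord cells enriched in motor neurons. PR20 is a peptide of repeated proline and arginine, a dipeptide that is also translated from the expanded repeat of C9ORF72. There was 1 library of untreated cells, called the control here, and there were 2 libraries of spontaneously PR20-resistant clones, called clone 1 and clone 2, for which the labels give 10 µM PR20 for 3 weeks. The control held 11700755 gene counts, clone 1 held 11389663 and clone 2 held 11307034, so 3 counts corresponded to 0.256, 0.263 and 0.265 CPM before TMM scaling. Nothing in the labels says that the clones came from separate cultures, and the p-values then measure only the spread between these libraries, which may be technical. Levels are given as CPM scaled by TMM factors, with the clones as mean ± SD (n = 2) and the control as a single value without a replicate.

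The first comparison asked which transcripts differed between the resistant clones and untreated cells. Of 45 tested genes on the neuronal cytoskeleton and synapse list, 38 fell and 1 rose. Vgf, which encodes a secreted neuropeptide precursor, stood at 2527 CPM in the control and at 32.8 ± 1.73 CPM in the clones, a log2 fold change of -6.27 ± 0.06 (SE; edgeR adjusted p = 1.09e-19). The neurofilament gene Nefh fell from 323 to 17.8 ± 0.875 CPM, and the synaptic genes Rab3c and Syt4 had no read in either clone. On the G2 and mitosis list 44 of 48 genes rose, and on the glycolysis and hypoxia list 25 rose and 4 fell of 37 (adjusted p = 0.689 with an estimated correlation for all 3 lists). Examples are Bub1b, a spindle checkpoint kinase gene, which rose from 70.2 to 142 ± 1.49 CPM, and Egln3, an oxygen-sensing prolyl hydroxylase gene, from 168 to 435 ± 3.19 CPM. Of 13705 genes tested, edgeR called 3332 higher and 3533 lower in the clones.

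The falls were larger than the rises. Among called genes, 1281 were at least 2-fold lower and 305 at least 2-fold higher, 545 were at least 4-fold lower and 65 at least 4-fold higher, and 199 against 5 passed 16-fold. Changes under 1.5-fold made up 55.4% of the calls. The median log2 fold change over all tested genes was 0.002. The authors' deposited table lists 2751 genes with an adjusted p under 0.05, of which 1392 were higher and 1359 lower, and edgeR called each of these 2751 in the same direction. That table rests on the same 3 libraries, and 4114 further edgeR calls did not reach an adjusted p of 0.05 in it.

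Among called genes with a mean of at least 5 CPM, predicted genes aside, the 10 that fell most by fitted fold change included 7 with no read in either clone. The fitted size of these 7 rests on no reads. Their rank against genes with reads, such as Stmn3 (log2 fold change -8.27), is therefore not established. Against a floor of 3 counts over both clones, Rab3c (ENSMUSG00000021700.10; GRCm38 chromosome 13, 110054187 to 110280996), a vesicle GTPase gene, was at least 431-fold lower, Syt4, a synaptotagmin gene, at least 273-fold, and the sialyltransferase gene St8sia3 at least 235-fold. The others were Xkr7 (at least 184-fold), Actl6b, a subunit of the neuronal BAF chromatin remodelling complex (at least 175-fold), Cacng3, an AMPA receptor auxiliary subunit gene (at least 137-fold), and Pet2 (at least 125-fold). Scg3, a granin gene, fell from 437 to 0.716 ± 0.131 CPM, the neurofilament gene Nefl from 139 to 0.268 ± 0.251 CPM (5 reads in clone 1 and 1 in clone 2), and Syp, which encodes synaptophysin, from 70.2 to 0.179 ± 0.001 CPM. The annotation places Nefl and Nefm on overlapping intervals of opposite strands, and the strand setting of the counting is not stated.

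Among called genes with a mean of at least 5 CPM, predicted genes aside, the 10 that rose most changed by less. Frk, a SRC-family kinase gene, rose from 0.832 CPM to 9.35 CPM in clone 1 and 8.99 CPM in clone 2, with a log2 fold change of 3.45 ± 0.35 (SE; edgeR adjusted p = 6.07e-07). Cdon (chromosome 9, 35421128 to 35507652), which encodes a hedgehog co-receptor, rose from 56.4 CPM to 300 and 276 CPM, a log2 fold change of 2.35 (edgeR adjusted p = 2.60e-13). Csf1, the macrophage colony-stimulating factor gene, rose from 44.9 to 184 and 175 CPM, and Atp2b3, a calcium pump gene, from 2.33 to 9.17 and 9.53 CPM. Pear1, Isg15, Vasn, Ttc23, Galnt4 and Pcdhb18 had log2 fold changes of 2.19, 2.17, 2.09, 2.02, 2.41 and 2.52. Pcdhb18, Galnt4, Cdon, Pear1, Vasn and Ttc23 overlap other annotated genes, and their counts may include reads of those genes.

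**Figure D1:**
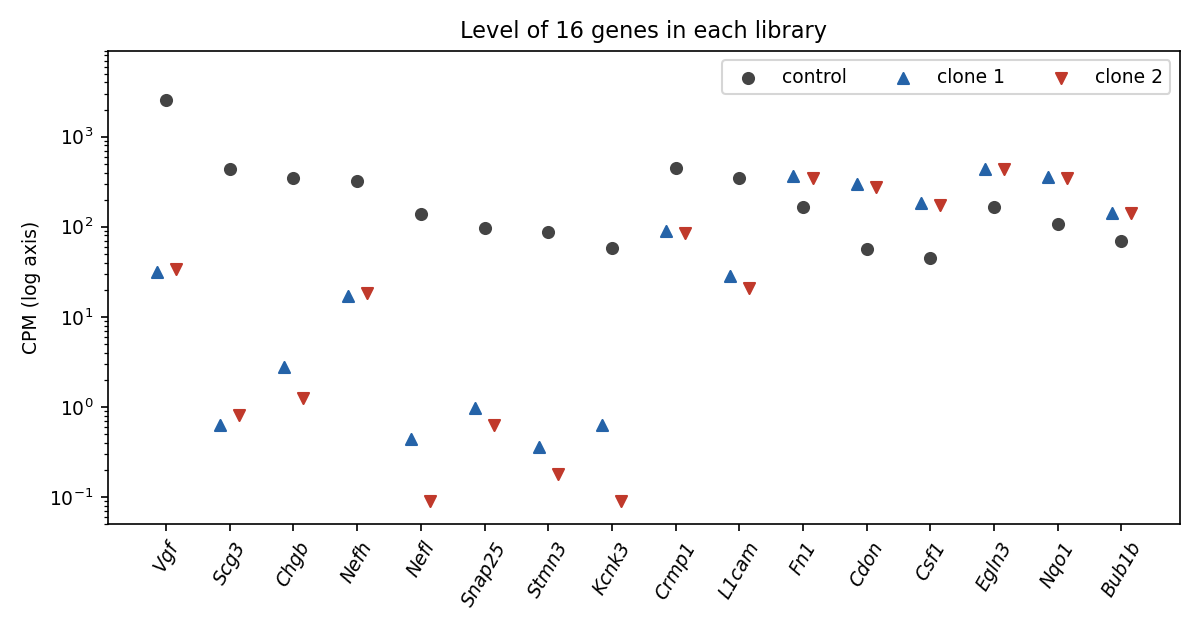
CPM on a log axis for 16 genes named by the rules, with 1 point per library (control, clone 1 and clone 2). Vgf stands at 2527 CPM in the control and at 31.6 and 34.1 CPM in the clones, and the clone points of each gene lie on the same side of the control.

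The 1 gene that rose on the neuronal cytoskeleton and synapse list was Mapt (log2 fold change 0.18), against 38 of 45 that fell. The median log2 fold change of the list was -2.12, and camera placed it below other genes (adjusted p = 2.13e-70; adjusted p = 0.689 with an estimated correlation). Snap25, a SNARE protein gene, fell from 98.0 to 0.804 ± 0.248 CPM and Stmn3, a microtubule regulator gene, from 86.5 to 0.268 ± 0.125 CPM. Prph, which encodes peripherin, had a log2 fold change of 0.09 and did not pass. Where no second count is given for a list, the counts adjusted over the list alone were identical.

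Of 25 genes on the noradrenergic and sympathetic identity list, 21 fell and 0 rose, with a median log2 fold change of -1.92 (camera adjusted p = 2.81e-48; adjusted p = 0.689 with an estimated correlation). This list held the granins Chgb, which fell from 347 to 2.01 ± 1.06 CPM, and Scg2, which fell from 83.7 to 0.403 ± 0.192 CPM. The motor neuron and cholinergic list had 11 genes lower and 3 higher of 22, or 12 and 3 adjusted over the list alone. It did not pass camera (adjusted p = 0.132; adjusted p = 0.689 with an estimated correlation) but passed camera on ranks (adjusted p = 0.0432) and fry (adjusted p = 0.0407). Slc18a3, the vesicular acetylcholine transporter gene, fell from 9.40 to 0.179 ± 0.125 CPM, Ache, which encodes acetylcholinesterase, fell from 46.1 to 19.7 ± 1.26 CPM, and Pax6, a progenitor transcription factor gene, rose from 26.0 to 45.1 ± 5.48 CPM.

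Potassium channel genes fell in 12 of 22 cases and rose in 0 (camera adjusted p = 0.00182; adjusted p = 0.689 with an estimated correlation). Kcnk3, which encodes a leak channel, fell from 57.9 to 0.357 ± 0.377 CPM. Axon guidance genes fell in 19 and rose in 8 of 34 cases (camera adjusted p = 0.00223; adjusted p = 0.689 with an estimated correlation). Crmp1, a semaphorin response gene, fell from 449 to 87.6 ± 2.53 CPM and the netrin receptor gene Unc5a from 34.7 to 0.717 ± 0.258 CPM. Integrin and adhesion genes fell in 14 and rose in 4 of 30 cases (camera adjusted p = 0.00182; adjusted p = 0.689 with an estimated correlation). L1cam, a neural adhesion molecule gene, fell from 346 to 24.5 ± 5.03 CPM and Itga1, the alpha 1 integrin gene, from 24.5 to 2.33 ± 0.521 CPM. Imprinted genes fell in 7 and rose in 3 of 18 cases, with 8 lower adjusted over the list alone (camera adjusted p = 0.0148; adjusted p = 0.689 with an estimated correlation), and Peg3 fell from 595 to 162 ± 1.99 CPM. Without genes on chromosomes 7, 15, 18 and X, a set chosen after seeing the data, the imprinted list no longer passed (camera adjusted p = 0.491).

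**Figure D2:**
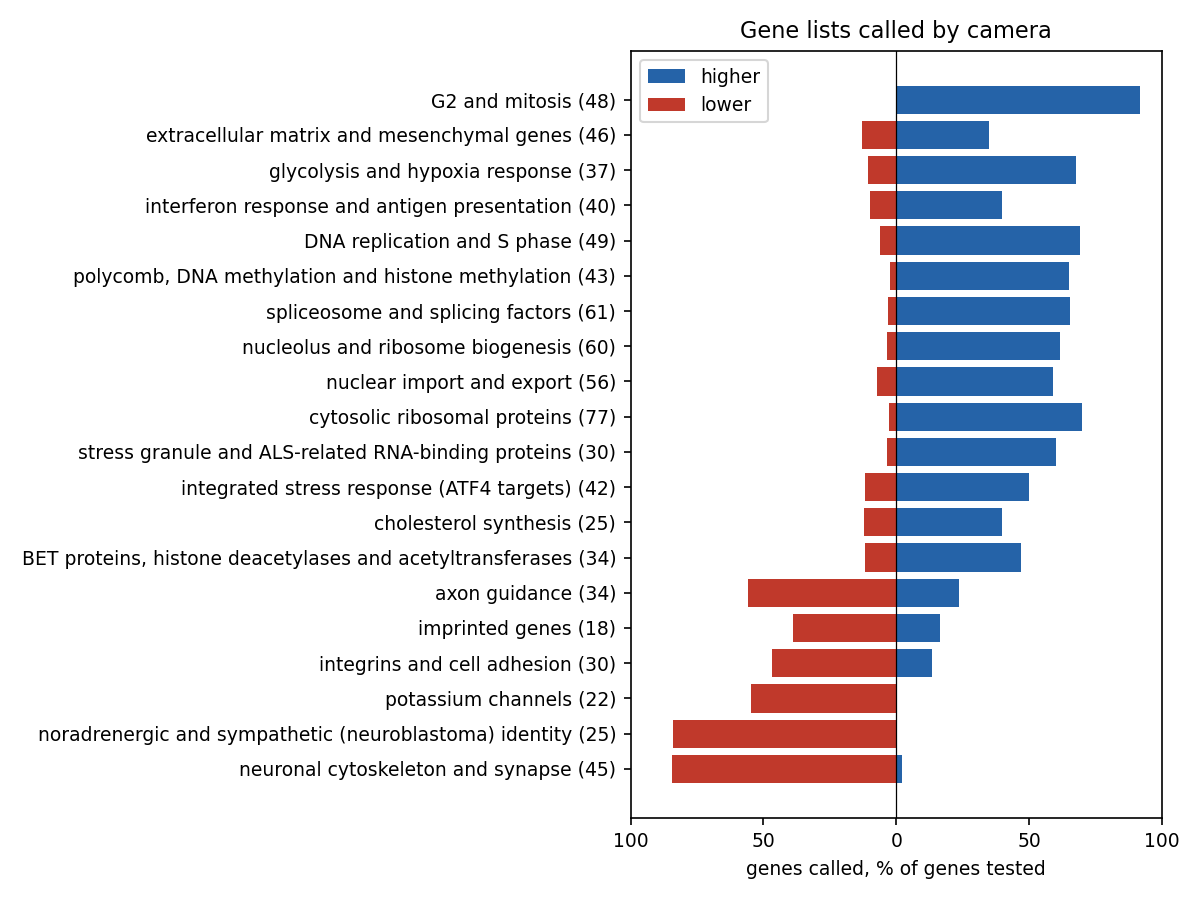
Share of tested genes called higher (right, blue) and lower (left, red) by edgeR in the 20 gene lists that passed camera with the preset correlation, with the number of tested genes in brackets. Bars run up to 44 of 48 genes higher on the G2 and mitosis list and 38 of 45 lower on the neuronal cytoskeleton and synapse list.

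Genes of G2 and mitosis rose in 44 of 48 cases and fell in 0, or 45 and 0 adjusted over the list alone. Their median log2 fold change was 0.60 (camera adjusted p = 2.66e-14; adjusted p = 0.689 with an estimated correlation). Kif20a, a mitotic kinesin gene, rose from 99.9 to 226 ± 22.9 CPM, and Foxm1, a transcription factor gene of the mitotic programme, from 63.0 to 124 ± 4.79 CPM. Genes of DNA replication and S phase rose in 34 and fell in 3 of 49 cases, with a median of 0.35 (camera adjusted p = 1.08e-07; adjusted p = 0.689 with an estimated correlation). Tk1, the thymidine kinase gene, rose from 73.3 to 137 ± 2.66 CPM. Replication-dependent histone genes had 2 tested members, neither of which was called, and the list was not tested as a set.

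Glycolysis and hypoxia genes rose in 25 and fell in 4 of 37 cases, with 5 lower adjusted over the list alone, and had a median log2 fold change of 0.44 (camera adjusted p = 6.05e-07; adjusted p = 0.689 with an estimated correlation). Pgk1, a glycolytic kinase gene, rose from 176 to 315 ± 0.800 CPM and Ldha, the lactate dehydrogenase A gene, from 922 to 1537 ± 18.8 CPM. Ldha is 1 of 5 genes of this list on chromosomes 7 and 18, all 5 of which rose. The list median off chromosomes 7, 15, 18 and X was 0.39. Cholesterol synthesis genes rose in 10 and fell in 3 of 25 cases (camera adjusted p = 0.0414; adjusted p = 0.689 with an estimated correlation). Without the chromosomes 7, 15, 18 and X the cholesterol list had an adjusted p of 0.0515.

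Of 77 ribosomal protein genes, 54 rose and 2 fell, with a median log2 fold change of 0.22 (camera adjusted p = 4.63e-06; adjusted p = 0.716 with an estimated correlation). Chromosomes 7 and 18, where the median log2 fold changes were 0.30 and 0.44, carry 16 of the 77, of which 15 rose, among them Rps16 (376 to 693 ± 2.22 CPM) and Rps14 (308 to 552 ± 8.77 CPM). The median of the ribosomal protein genes off chromosomes 7, 15, 18 and X was 0.20. Of 60 nucleolar and ribosome biogenesis genes, 37 rose and 2 fell, or 38 and 2 adjusted over the list alone (camera adjusted p = 5.80e-06; adjusted p = 0.689 with an estimated correlation). Ubtf, which encodes an RNA polymerase I factor, rose from 165 to 252 ± 3.30 CPM. Of 61 splicing genes, 40 rose and 2 fell (camera adjusted p = 1.29e-05; adjusted p = 0.689 with an estimated correlation), and Prpf19 rose from 218 to 348 ± 0.460 CPM. Of 56 nuclear import and export genes, 33 rose and 4 fell, or 35 and 4 adjusted over the list alone (camera adjusted p = 8.61e-05; adjusted p = 0.689 with an estimated correlation). The nucleoporin genes Nup188 and Nup62 rose from 119 to 206 ± 4.80 CPM and from 101 to 170 ± 3.13 CPM. Of 30 stress granule and ALS-related RNA-binding protein genes, 18 rose and 1 fell (camera adjusted p = 0.00399; adjusted p = 0.689 with an estimated correlation), and Ewsr1 rose from 277 to 374 ± 14.2 CPM.

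Among chromatin genes, the list of polycomb, DNA methylation and histone methylation had 28 higher and 1 lower of 43 (camera adjusted p = 0.000240; adjusted p = 0.689 with an estimated correlation). Dnmt1, the maintenance DNA methyltransferase gene, rose from 295 to 465 ± 7.36 CPM, and Kmt2b, a histone methyltransferase gene on chromosome 7, from 61.7 to 119 ± 0.241 CPM. The list of BET proteins, histone deacetylases and acetyltransferases had 16 higher and 4 lower of 34 (camera adjusted p = 0.0430; adjusted p = 0.689 with an estimated correlation). Hdac3, a histone deacetylase gene on chromosome 18, rose from 91.8 to 138 ± 0.941 CPM. Protein arginine methyltransferase genes had 5 higher and 3 lower of 12 and did not pass camera (adjusted p = 0.231), and Prmt1 rose from 121 to 222 ± 6.06 CPM. Prmt1 is 1 of 2 genes of this list on chromosomes 7 and 18, and both rose. The list median off chromosomes 7, 15, 18 and X was -0.04.

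ATF4 targets of the integrated stress response rose in 21 and fell in 5 of 42 cases (camera adjusted p = 0.00399; adjusted p = 0.689 with an estimated correlation). Chromosomes 7 and 18 carry 5 of them, of which 4 rose. The median log2 fold change was 0.60 there and 0.16 off chromosomes 7, 15, 18 and X. Atf5 rose from 153 to 315 ± 0.650 CPM and Phgdh, an enzyme gene of serine synthesis, from 225 to 365 ± 22.0 CPM, while Stc2 fell from 78.9 to 28.5 ± 3.93 CPM. The list of the endoplasmic reticulum unfolded protein response had 17 genes lower and 1 higher of 27, or 17 and 3 adjusted over the list alone. It did not pass camera (adjusted p = 0.0674), also not with an estimated correlation (adjusted p = 0.689) or without chromosomes 7, 15, 18 and X (adjusted p = 0.163). It passed camera on ranks (adjusted p = 0.0110) and fry (adjusted p = 0.0499). Hspa5, the ER chaperone BiP gene, fell from 1612 to 1259.8 ± 14.5 CPM. NRF2 targets had 8 higher and 10 lower of 33 (camera adjusted p = 0.551), including Nqo1, a quinone reductase gene, which rose from 107 to 354 ± 7.19 CPM.

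Extracellular matrix and mesenchymal genes rose in 16 and fell in 6 of 46 cases (camera adjusted p = 0.0125; adjusted p = 0.689 with an estimated correlation). Fn1, the fibronectin gene, rose from 164 to 357 ± 19.1 CPM. Fibroblast markers had 2 higher and 2 lower of 8, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.551), and Pdgfrb rose from 5.66 to 13.3 ± 1.23 CPM. Pdgfrb is the only tested gene of this list on chromosomes 7 and 18. Interferon response and antigen presentation genes rose in 16 and fell in 4 of 40 cases (camera adjusted p = 0.0430; adjusted p = 0.689 with an estimated correlation). Bst2, an interferon-induced gene, rose from 27.8 to 94.6 ± 4.98 CPM, while the class I antigen gene H2-D1 fell from 180 to 65.2 ± 4.83 CPM. H2-D1 shares sequence with other class I genes, and its counts are uncertain for that reason. The interferon list had an adjusted p of 0.0588 without chromosomes 7, 15, 18 and X.

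Lists tied to uptake, cell surface sugars and clearance moved in both directions and did not pass camera. Heparan sulfate genes had 14 higher and 10 lower of 36 (adjusted p = 0.572; 0.0407 with fry), with Hs6st1 rising from 381 to 651 ± 3.62 CPM and the glypican gene Gpc4 falling from 78.6 to 14.2 ± 1.93 CPM. Chondroitin sulfate genes had 4 higher and 4 lower of 16 (adjusted p = 0.176; 0.0499 with fry and 0.0296 without chromosomes 7, 15, 18 and X), and Bcan, the brevican gene, fell from 52.9 to 1.66 ± 0.454 CPM. Endocytosis genes had 14 higher and 14 lower of 48, or 15 and 14 adjusted over the list alone (adjusted p = 0.796). Lysosome and autophagy genes had 10 higher and 20 lower of 57 (adjusted p = 0.132), proteasome genes 9 higher and 16 lower of 38 (adjusted p = 0.689), and cytosolic chaperone genes 10 higher and 17 lower of 41 (adjusted p = 0.474). Of the ABC efflux transporter genes, 2 were higher and 8 lower of 23 (adjusted p = 0.132), and Abcb1a, which encodes a P-glycoprotein, fell from 16.5 to 3.85 ± 0.608 CPM.

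The remaining lists did not pass camera. Translation factor genes had 17 higher and 7 lower of 44 (adjusted p = 0.317), MYC and its targets 13 higher and 4 lower of 25, with 5 lower adjusted over the list alone (adjusted p = 0.123; 0.0407 with fry), and nuclear-encoded oxidative phosphorylation genes 23 higher and 14 lower of 76 (adjusted p = 0.407). Mitochondrially encoded genes had 2 higher and 5 lower of 13 (adjusted p = 0.812), p53 targets 10 higher and 13 lower of 33 (adjusted p = 0.887), and BCL2 family and caspase genes 11 higher and 10 lower of 35, with 12 higher adjusted over the list alone (adjusted p = 0.515). Serum and immediate early genes had 11 higher and 9 lower of 32, with 10 lower adjusted over the list alone (adjusted p = 0.216; 0.0407 with fry), and Egr1 rose from 86.2 to 218 ± 4.96 CPM. The median log2 fold change of this list was 0.99 for its 3 genes on chromosomes 7 and 18. It was -0.12 off chromosomes 7, 15, 18 and X. Glial markers had 1 higher and 4 lower of 10 (adjusted p = 0.647), and epithelial markers 0 higher and 2 lower of 9 (adjusted p = 0.829). Blood and endothelial markers had 0 higher and 2 lower of 3 and were not tested as a set. Median, mean and test did not share a sign for the heparan sulfate, chondroitin sulfate, p53, BCL2, NRF2, mitochondrially encoded and immediate early lists.

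The spread behind these edgeR calls came from the 2 clones alone, with 1 residual degree of freedom and a biological coefficient of variation of 3.37%, and the single control was assumed to vary like the clones. Without the low-count filter edgeR called 4 genes. DESeq2, whose spread also came from the clones alone, called 2771. Of these, 35 neuronal genes were lower, and 37 G2 and mitosis genes were higher and 0 lower. Higher and lower were 35 and 0 ribosomal protein, 25 and 0 splicing, 22 and 2 nuclear transport and 24 and 1 S phase genes. Polycomb genes numbered 11 and 0, stress granule genes 11 and 0 and ATF4 targets 15 and 2. With a variation preset at 20%, chosen after seeing the data, 156 genes were higher and 992 lower. These included 30 lower neuronal genes, 1 higher G2 and mitosis gene and 3 higher glycolysis and hypoxia genes. They included 0 higher ribosomal protein, splicing, nuclear transport, S phase, polycomb, stress granule or ATF4 target genes.

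The second comparison asked which genes moved at least 2-fold from the control in both clones, a rule of size without a test. The lower side held Vgf, at log2 ratios of -6.32 and -6.21 in clones 1 and 2, and Cdon and Csf1 stood on the higher side. By this rule 289 genes were higher and 1135 lower in both clones. Clone 1 alone had 426 higher and 1382 lower, and clone 2 alone had 456 higher and 1416 lower. Independent lists of these sizes would share 14.2 higher and 143 lower genes. Simulated clones with no effect, set against a shared simulated control, had 45.8 and 19.8 genes in common. The higher count was 190 with a prior count of 5, and without the low-count filter the counts were 1222 higher and 1974 lower.

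The changes of the clones were close to each other across genes. Pearson's r across genes of the log2 ratios was 0.934, or 0.785 without the low-count filter, and 88.5% of genes had the same sign in both clones. Simulated clones without any effect, measured against a shared simulated control, gave an r of 0.487 and 66.3% of genes with the same sign. The simulated control was given the spread of the clones, and a control that varies more would raise these values. The covariance was 0.885, against 0.043 in the simulation, a difference of 0.842. Genes are not independent replicates, and since the single control cannot be split, part of the excess in r and in shared genes may come from it.

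**Figure D3:**
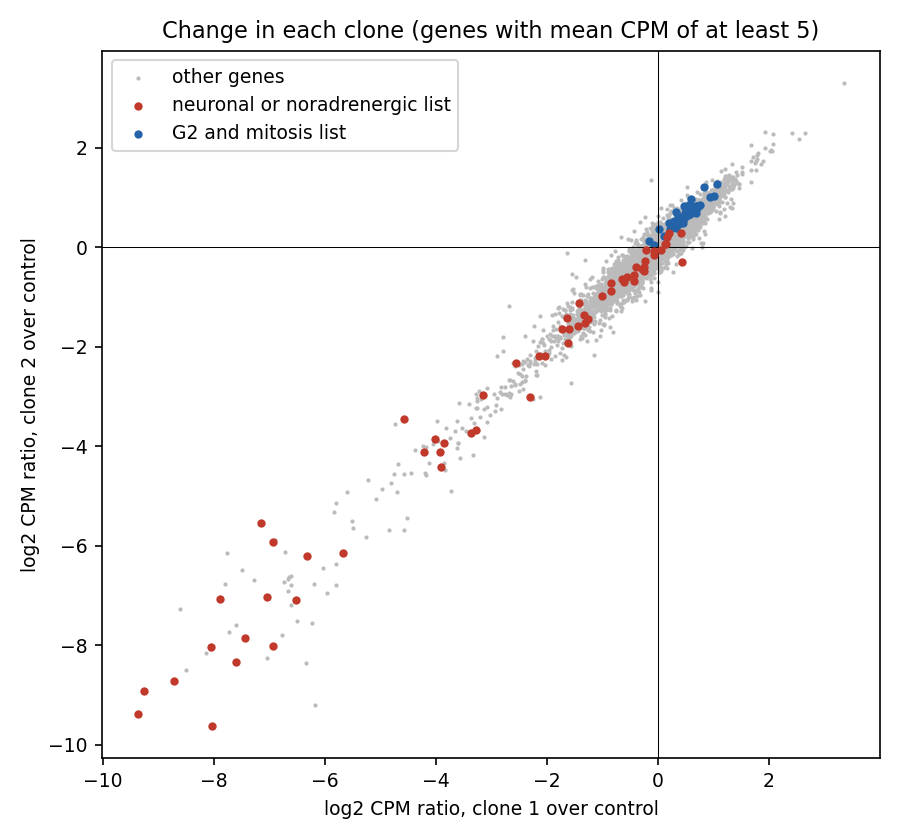
Log2 CPM ratio of clone 1 (x axis) and clone 2 (y axis) to the control, 1 point per gene with a mean CPM of at least 5. Genes of the neuronal and noradrenergic lists (red) extend to the lower left, and G2 and mitosis genes (blue) lie mostly above 0 on both axes.

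The third comparison set clone 2 against clone 1, 1 library each, so values are given without a test. Few well-covered genes differed. Rn7sk, a small nuclear RNA gene, stood at 14.7 CPM in clone 2 and 5.17 CPM in clone 1, a log2 ratio of 1.49 (95% exact binomial interval for counting error 1.06 to 1.96). Metrnl, Thy1, Apoe and Rpl37rt were the next highest in clone 2, with log2 ratios of 0.87, 0.86, 0.85 and 0.77, and Gpr22, Oasl2, Zbtb42 and Klf3 were among the highest in clone 1, with log2 ratios of -0.85, -0.79, -0.77 and -0.74. Gm42418, chosen after its values were seen, took 0.0483% of counts in clone 1, 0.138% in clone 2 and 0.156% in the control. Of 13705 genes, 240 were at least 2-fold higher in clone 2 and 198 in clone 1, and of 10258 genes with a mean of at least 5 CPM in the clones, only Rn7sk and Gm42418 were 2-fold apart. The count of 438 genes fell to 183 with a mean CPM of at least 1 and to 120 with a prior count of 5, and rose to 5046 without the low-count filter.

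The clones differed by more than counting noise. Over 12710 genes with at least 20 reads, the chi-square per gene was 2.39, and 287 genes lay beyond counting noise after Benjamini-Hochberg adjustment, so the clones were counted as 2 libraries. The control against clone 1 and clone 2 gave 44.1 and 45.4 per gene. These tests on reads compare libraries, not conditions.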

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

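The preset variations, the removal of chromosomes 7, 15, 18 and X, the unfiltered legacy fit, the unfiltered correlation of the clones and the estimate used with a clone left out were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The 6865 calls became 6554 with RLE factors, 6364 with limma-voom, 6812 with the robust and 6693 with the legacy fit. DESeq2 called 2771 genes, 1402 higher and 1369 lower, all in the direction of the edgeR calls. Without a low-count filter edgeR called 4 genes, 0 higher and 4 lower, the median prior degrees of freedom of the quasi-likelihood fit were 1.16 in place of 14.6, and 7086 genes had an unadjusted p under 0.05. With the legacy fit and no filter there were 0 calls, 0 higher and 0 lower. A preset variation of 10% gave 3617 calls, 1436 higher and 2181 lower, and one of 20% gave 1148, with 156 higher and 992 lower, which moved the share of higher calls from 48.5% to 13.6%. Apart from the filter, the cause of these moves was not tested.

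Genes 2-fold from the control in both clones numbered 1222 higher and 1974 lower without a filter and 190 higher with a prior count of 5. In a single clone they numbered 426 to 456 higher and 1382 to 1416 lower. Genes 2-fold apart between the clones numbered 5046 without a filter, 183 with a mean CPM of at least 1 and 120 with a prior count of 5. The correlation of the clones' changes was 0.954 and 0.948 under the latter settings and 0.785 without a filter. The cause was not tested. Of 20 lists that passed camera, 0 passed with an estimated correlation (adjusted p = 0.689, or 0.716 for ribosomal proteins), a setting with 1 residual degree of freedom and little power. Of the 41 lists tested, 12 passed fry. The fry adjusted p was 0.190 for G2 and mitosis, 0.130 for S phase, splicing, axon guidance and stress granules, 0.152 for ribosomal proteins, 0.108 for the nucleolus and for BET proteins and deacetylases, 0.112 for nuclear transport, 0.0547 for polycomb, 0.0696 for ATF4 targets, 0.193 for matrix, 0.0533 for imprinted and 0.142 for interferon genes. The imprinted list had an adjusted p of 0.163 with camera on ranks and 0.491 without chromosomes 7, 15, 18 and X, where cholesterol synthesis had 0.0515 and interferon genes 0.0588. Lists that passed only under an alternative were ER unfolded protein response (0.0110 on ranks, 0.0499 with fry), motor neuron (0.0432 on ranks, 0.0407 with fry), chondroitin sulfate (0.0296 without those chromosomes, 0.0499 with fry), and MYC, immediate early and heparan sulfate genes (0.0407 with fry). Of 185 named genes, 180 were called by edgeR, and 11 of these were not called by DESeq2. Without clone 1 and without clone 2, the edgeR estimates of 5 and 3 named genes moved by more than their spread. That spread was the larger of the SD of the clones and the standard error. Leaving out 1 of 2 clones moves most estimates by less than that SD, so these counts are no measure of stability. No called gene reversed there, with RLE factors or with DESeq2. The uncalled Hist1h1c and Hist1h2bc changed sign with a clone left out. Among the genes that moved, Nefl went from a log2 fold change of -8.96 to -10.43 without clone 1 and stood at -8.25 without clone 2. Kcnk3, Stmn3 and Slc18a3 also moved without clone 1. Depth limits genes near 3 counts.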

Other observations

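The edgeR test and the neuronal list were planned. All other tests in this part, and the genes it singles out, were chosen only after results were seen. Ass1, which encodes argininosuccinate synthase, stood at 324 CPM in the control and at 1312 and 1235 CPM in clones 1 and 2 (edgeR adjusted p = 1.52e-13), while Asl, the gene of the next enzyme, stood at 112 CPM and at 44.9 and 42.8 CPM (edgeR adjusted p = 3.60e-10). Nos1 went from 3.25 to 1.07 and 0.539 CPM, and the transporter genes Slc7a1 and Slc7a3 had log2 fold changes of 0.27 and 0.97. The WNT antagonist gene Dkk1 went from 172 CPM to 11.8 and 8.45 CPM, and Lin28a from 23.3 to 0.267 and 0.180 CPM. Smad3, a TGF-beta signal transducer gene, had a log2 fold change of 1.82 and Igf1r, the IGF1 receptor gene, of 1.38. Clustered protocadherin genes, which overlap in the annotation and share sequence, went both ways: Pcdhb14 and Pcdhb20 had log2 fold changes of 1.67 and 1.38, and Pcdhb11 and Pcdha9 of -2.67 and -4.06. The repressor gene Rest stood at 42.4 CPM in the control and at 83.5 and 74.3 CPM in the clones (edgeR adjusted p = 4.60e-07), its corepressor gene Rcor2 at 76.5, 111 and 112 CPM, and Srrm4, a neuronal splicing factor gene, had a log2 fold change of -5.61.

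Of 45 genes on the neuronal list, 38 were lower in the clones. If the clone libraries came from cells of a lineage without the control's lineage transcription factors, these factors would be lost. The 18 such genes chosen, with at least 5 CPM in the control, had a median log2 change of -0.34 (bootstrap interval over these genes -0.89 to -0.12). Of them, 13 stayed within 2-fold and 5 fell more than 2-fold. A lineage that shares these factors cannot be excluded by this test. Gata2 stood at 245 CPM in the control and at 234 and 232 CPM in the clones, although Insm1 had a log2 fold change of -3.98. Among all 117 genes with a mean of at least 5 CPM that fell at least 8-fold, 2 pairs were neighbours. The mean was 1.33 and the highest 6 in 1000 random placements. For these 117 genes, this argues against loss of chromosome segments that hold several of them. The count was not limited to the neuronal list. It cannot show losses that lower genes by less than 8-fold, such as the falls on distal X described below. Stronger repression of REST targets cannot be told apart from a general fall: 20 literature REST targets had a median log2 change of -2.21 and 36 other neuronal genes of -1.94, a difference of -0.26 (one-sided permutation p = 0.435 over 100000 resamples). A less neuronal subpopulation from which the clones arose, growth in culture and the response to PR20 itself all stay open and may act together, since there was 1 untreated library and no clone without PR20.

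Median changes of genes on some chromosomes lay away from 0 in both clones. Among genes with a mean of at least 5 CPM, the median log2 fold change was 0.44 over 265 genes on chromosome 18, 0.30 over 808 on chromosome 7, 0.15 over 527 on chromosome 17, -0.24 over 419 on chromosome 15 and -0.22 over 321 on X. In 5 segments of X, cut after the values were seen, the medians were -0.08, 0.07, -0.43, -0.99 and, from position 151046150 onward, -1.18. The medians of chromosomes 7, 15, 17, 18 and X, and the small ones of 5 (-0.05) and 10 (-0.06), lay outside 10000 random lists of their sizes. GC content or transcript length bias was argued against, since the chromosome 18 median was 0.44 after a trend on both was removed and the highest of the random lists was 0.14. A change in DNA copy number of chromosome 18 is a candidate explanation that cannot be told apart from others here: the lowest of its 8 windows of 60 genes had a median of 0.28, while the highest window off chromosomes 7 and 18 reached 0.31, and DNA was not analysed here. The copy number prediction was written only for chromosome 18 and was not applied to chromosomes 7, 15, 17 and X. On chromosome 15 all 13 windows had medians below 0, from -0.40 to -0.13. The lowest window off chromosomes 15 and X reached -0.24. In the last segment of X, 42 of 49 genes were called lower. Windows on chromosome 7 had medians from 0.04 to 0.59. No other biological explanation was tested.

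The clone libraries differed by more than counting noise (chi-square per gene 2.39), but far less than either differed from the control (44.1 and 45.4). A single library sequenced or deposited more than once was argued against by a chi-square per gene of 1.85 without mitochondrial genes, Gm42418 and Rn7sk, with 266 genes beyond counting noise. Sister cultures of 1 resistant cell and separate clones that reached a like state both stay open and were not tested; they may differ little in RNA.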
